A study of Mus musculus with 12 samples.

How the data were processed

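RNA sequencing was carried out on blood and spleen of wild-type (WT) mice and of mice lacking nuclear myosin 1 (KO), with 3 libraries in each of the 4 groups. Per the labels, the C57/Bl6 mice were 8 months old, blood came from the submandibular vein, and a piece of about 5 mm3 was taken from the tip of the spleen. Libraries were made with the NEBNext Ultra II RNA kit from 500 ng of total RNA and sequenced on a NextSeq instrument. Per the labels, 3 replicates were prepared for each genotype, but whether every library came from a separate mouse was not stated. The p-values therefore measure the spread between these libraries.

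The deposited values are raw counts per gene, 1 table per library, with 46603 Ensembl mouse gene identifiers in each. The submitters' processing notes name Trimmomatic 0.36, FastQC, HISAT2 2.0.4, SAMtools 0.1.19 and HTSeq, with the builds GRCm38 and mm10. The annotation release and the strand setting of the counting step were not given. Symbols and positions were taken from the GENCODE vM21 annotation of GRCm38, which held 46005 of the identifiers. Klkb1 and Ahsp, each a member of a gene list, had no matching identifier.

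Total counts ranged from 9.32 to 12.1 M in 6 libraries and from 23.1 to 28.2 M in the other 6. A gene with 0 counts could hold up to 3 counts by chance, which is 0.106 to 0.322 CPM (counts per M counts) depending on the library. Shares of counts given for single libraries carry 95% Wilson intervals, and the widest globin interval was ± 0.035 percentage points. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. A comparison of counts of at least 20 between every pair of libraries showed no duplicated library (smallest chi-square per degree of freedom 7.17).

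Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. For each tissue, genes were kept with filterByExpr, scaled with the trimmed mean of M-values (TMM) and tested by edgeR's quasi-likelihood F test with robust dispersions. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A difference between the KO effects of the tissues was tested as the interaction in a fit of all 12 libraries. Gene effects are log2 fold changes of KO over WT ± SE, and group values are TMM-scaled mean CPM ± SD.

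For cell types and pathways, 33 gene lists were fixed, and those with at least 5 tested members were tested by camera with a preset inter-gene correlation of 0.01. Each test was repeated with an estimated correlation, and fry was run beside it. Genes of a list were also adjusted over the list alone. Named genes followed a fixed rule. The rule took Myo1c, then called genes with a mean of at least 1 CPM whose KO libraries all lay on 1 side of the WT libraries. Predicted gene models, pseudogenes and receptor segments were excluded. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given as values. From every list up to 2 members with the smallest p were taken when none passed. The comparisons, gene lists, naming rule and alternatives were set before the data were examined.

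A term for library kind was added after the counts were seen. A library was called globin-rich when globin took over 25% of its counts and globin-poor otherwise. The same genotype test was then run within the 6 libraries of each kind. No library was left out of the planned comparisons, and every library kept its label. Shares of counts were compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow. Genes within 10 Mb of Myo1c were compared with all others by Fisher's exact test.

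The alternatives tried were DESeq2 size factors, library size only, TMM without globin and mitochondrial genes, no filter, a filter of 5 CPM in 3 libraries, DESeq2, limma-voom, non-robust dispersions, a 1.5-fold minimum, 1 fit of all 12 libraries, a replicate block and leaving out each library. Some replicate numbers are shared between groups, but the labels do not say that a number marks 1 mouse. Correlations of residual expression followed library kind rather than the shared number. A limma-voom fit with duplicateCorrelation over genotype and number gave a consensus correlation of -0.058. Blood and spleen libraries with a shared number correlated at -0.75 and -0.46 where their kinds differed and at 0.64 and 0.57 where they matched. That fit had no kind term, so it cannot tell whether a number marks 1 mouse. The main comparisons were left unpaired because the labels name no pairs.

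The fits were tested on simulated data drawn from the means and library sizes of these libraries, with 200 genes altered by known folds. In blood with genotype as the only term, over 14425 genes, 0% of genes altered 2-fold, 4-fold or 8-fold were called. With the kind term, over 14792 genes, 34.3%, 85.1% and 93.9% were called, beside 15 unaltered genes. In spleen with genotype alone, over 14986 genes, 0% were called at each fold, and with the kind term, over 15306 genes, 14.9%, 64.2% and 78.8%, beside 20 unaltered genes. Within globin-rich libraries (11106 genes) 17.9%, 68.7% and 69.7% were called, and within globin-poor libraries (16125 genes) 7.46%, 76.1% and 87.9%. All 12 simulated sets of 30 genes altered 2-fold were found in the right direction, with the preset and with the estimated correlation. The simulated genes varied independently of each other. These sets therefore do not show how often the estimated correlation would find a list whose genes move together.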

Results

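The libraries profiled messenger RNA in blood and spleen of WT and KO mice. The KO mice lack nuclear myosin 1 (NM1), a form of the class I myosin Myo1c that acts in the nucleus with RNA polymerases. The groups were WT blood, KO blood, WT spleen and KO spleen, with 3 libraries each. The study's title names platelet activation and the immune response as its subject, so genes of platelets and of immune cells were of first interest. Total counts ranged from 9.32 M (M, 10 to the power of 6) in the library labelled spleen WT 04 to 28.2 M in spleen KO 01.

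Red cell genes divided the libraries before genotype did. Globin, the oxygen carrier of red cells, took 48.9% to 56.1% of counts in 6 libraries and 0.846% to 5.89% in the other 6. The globin-rich libraries were those labelled blood WT 01, blood KO 02, blood KO 03, spleen WT 02, spleen WT 04 and spleen KO 03. Vcam1, Spic and Cd5l, made by the red pulp macrophages that clear old red cells in the spleen, were nearly absent from them. Vcam1 lay between 0 and 0.877 CPM there against 188 to 405 CPM in the globin-poor libraries. It had 0 counts in blood KO 03 and spleen KO 03, which allows up to 0.270 and 0.248 CPM. Spic, a transcription factor needed for red pulp macrophages, lay between 0.107 and 0.809 CPM against 43.7 to 58.8 CPM. The macrophage gene Cd5l lay between 0.165 and 1.72 CPM against 44.0 to 70.3 CPM. The fixed list of red pulp macrophage and iron genes as a whole went the other way, with sums of 11400 to 18200 CPM in globin-rich and 5190 to 8830 CPM in globin-poor libraries, globin left out.

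Other cell types followed the same division. Platelet markers summed to 6140 to 17900 CPM in the globin-rich and 983 to 1410 CPM in the globin-poor libraries, with globin left out. Stromal and endothelial markers summed to 138 to 252 CPM against 2290 to 5030 CPM, and plasma cell markers to 1190 to 2560 CPM against 7100 to 22700 CPM. Each kind held 3 WT and 3 KO libraries and both tissue labels. Of the libraries labelled blood, 3 were globin-poor (WT 03, WT 04 and KO 04), and of those labelled spleen, 3 were globin-rich. Within a kind the tissue labels still differed in places: platelet markers summed to 17100 CPM or more in globin-rich libraries labelled spleen and to 10200 CPM or less in those labelled blood. In globin-poor libraries the erythroid sum was 24600 to 28000 CPM under the blood label and 2450 to 13300 CPM under the spleen label.

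**Figure D1:**
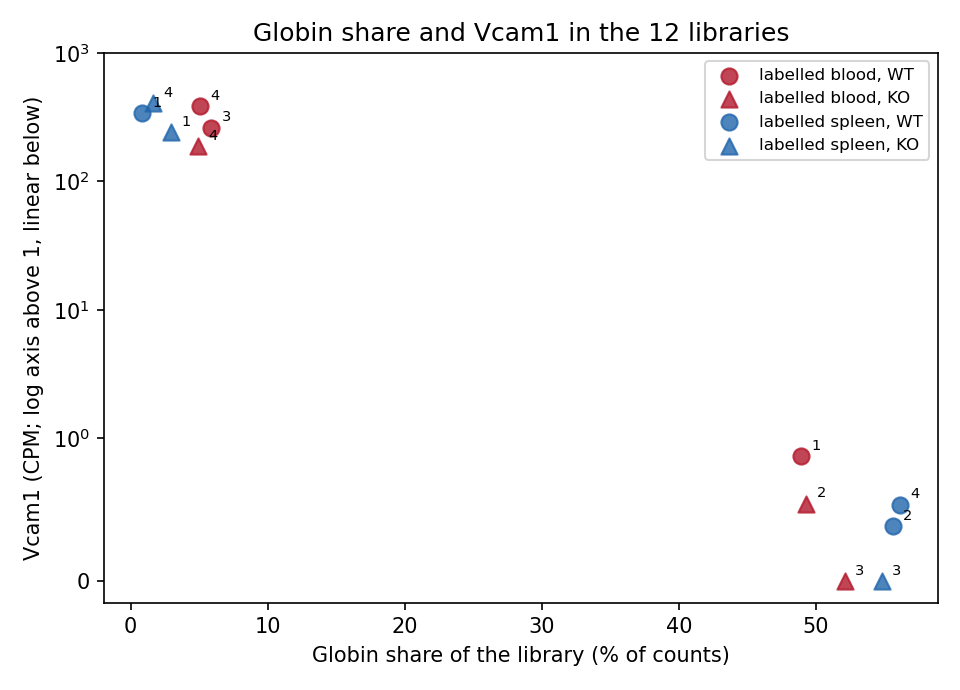
Globin share of counts (percent) against Vcam1 (CPM, log axis above 1 and linear below) in the 12 libraries, with colour for the tissue label, shape for genotype and the replicate number beside each point. 6 libraries, 3 of each tissue label, lie above 48% globin with Vcam1 at or under 0.877 CPM, and the other 6 lie under 6% with Vcam1 at or above 188 CPM.

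Myo1c itself was detected in every library. Before scaling it stood at 91.4, 153 and 208 CPM in WT blood, at 101, 74.5 and 142 CPM in KO blood, at 178, 26.0 and 30.5 CPM in WT spleen and at 130, 58.0 and 167 CPM in KO spleen, in the order of the replicate numbers. Myo1c (ENSMUSG00000017774) lies on the plus strand of chromosome 11 of GRCm38, from 75650504 to 75673910. Its scaled mean was 113 ± 31.6 CPM in WT and 142 ± 55.0 CPM in KO blood (SD, n = 3), and 77.8 ± 6.44 CPM in WT and 74.9 ± 22.9 CPM in KO spleen. The log2 fold change was 0.33 ± 0.43 (SE) in blood and -0.06 ± 0.29 in spleen, with adjusted p-values of 1 and 0.999. NM1 is 1 of several forms made from Myo1c, and a gene-level count sums all of them. These values therefore check neither the knockout nor the genotype labels.

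The blood comparison asked which cell types and pathways of blood differ without NM1. Platelet, T cell and natural killer genes stood higher in KO than in WT blood, and stromal, cell cycle and red pulp macrophage genes stood lower, by list tests that were all lost with an estimated correlation (smallest adjusted p = 0.623). WT blood held 1 globin-rich library against 2 in KO blood, and platelet, stromal and cell cycle sums did not overlap between the library kinds. T cell sums (1030 to 1860 CPM in globin-rich and 1470 to 3400 CPM in globin-poor libraries) and natural killer sums (257 to 511 and 325 to 675 CPM) did overlap. Both sums also overlapped between WT and KO within blood. With library kind as a term, the genes of neutrophils, the granule-bearing first responders to infection, stood lowest, and the platelet difference changed sign.

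By numbers, the platelet and megakaryocyte markers in blood had a median log2 fold change of 0.76, with 26 of 30 members above 0 (camera adjusted p = 2.3e-05). T cell markers had a median of 0.45 (adjusted p = 4.95e-08) and cytotoxic and natural killer markers of 0.59 (adjusted p = 7.83e-08). T cell sums, globin left out, were 1520, 1760 and 1470 CPM in WT and 1860, 1420 and 1580 CPM in KO blood. Natural killer sums were 443, 351 and 409 CPM in WT and 478, 419 and 325 CPM in KO blood. Stromal and endothelial markers had a median of -1.20, with 31 of 32 members below 0 (adjusted p = 3.41e-10). Cell cycle genes had a median of -0.62 (adjusted p = 0.000769) and red pulp macrophage and iron genes of -0.92 (adjusted p = 0.00228). In all, 15 of 33 lists passed, 9 up and 6 down. None passed with an estimated correlation, where the smallest adjusted p was 0.623, or by fry, where it was 0.802. For the nuclear-encoded oxidative phosphorylation genes and the cytosolic ribosomal proteins, which did not pass, camera pointed up while the medians were -0.05 and -0.06.

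With the kind term, platelet markers in blood had a median of -0.23, with 29 of 30 members below 0. Stromal markers lay at -0.36, cell cycle genes at 0.27 and T cell markers at 0.22. Neutrophil granule and maturation genes had a median of -0.64, with 25 of 26 members below 0, where genotype alone gave -0.38. Genotype alone gave 0.26 without WT 01 and 0.00945 with the replicate number as a block. The kind term gave -0.78 to -0.56 without each library in turn, but it then rests on KO 04 as the lone KO library without WT 01 (-0.67) and on WT 01 as the lone WT library without KO 04 (-0.56). Of these genes 8 were called when adjusted over the list alone and 0 over all genes. Oxidative phosphorylation genes had a median of 0.41, with 74 of 76 above 0. The neutrophil list gave an adjusted p of 0.422 with an estimated correlation, and 0.39 was the smallest of any list in this fit.

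No single gene passed in blood. edgeR called 0 of 14939 tested genes, and 24 had an unadjusted p under 0.05, where chance gives 747. DESeq2 and limma-voom also called 0, with 54 and 42 genes at an unadjusted p under 0.05. Over the list alone, 0 members of any list were called. Adding the kind term left 0 called of 16505 genes, with 340 at an unadjusted p under 0.05. In simulated data, genotype alone found none of the genes altered 8-fold in blood, so a count of 0 there says little.

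Blood genes taken by the naming rule, from the smallest p and from the lists, are given as values only. The neutrophil iron-binding protein Lcn2 (ENSMUSG00000026822, minus strand of chromosome 2, 32384633 to 32388252) averaged 26.5 ± 10.6 CPM in WT and 13.4 ± 2.3 CPM in KO blood (SD, n = 3). Its log2 fold change was -0.98 ± 0.39, and -0.95 ± 0.31 with the kind term. Hdc, which makes histamine in basophils and neutrophils (ENSMUSG00000027360, minus strand of chromosome 2, 126593667 to 126619299), stood at -0.79 ± 0.62, and at -1.44 ± 0.29 with the kind term. The decoy receptor Il1r2 stood at -1.24 ± 0.60 and the eosinophil receptor Ccr3 at -1.12 ± 0.45. App, carried in platelet granules, stood at -0.84 ± 0.32, and the neural adhesion gene Sdk2 at -1.88 ± 0.65. Rasl12, Sema6b and Ptgfrn lay between -1.98 and -1.41. On the higher side stood the chemokine Ccl4 at 1.84 ± 0.69, from 0.542 ± 0.165 to 1.98 ± 0.858 CPM, and pyruvate carboxylase, Pcx, at 1.09 ± 0.47. The histone genes Hist3h2ba and Hist1h4h and the gene Mdm1 lay between 1.06 and 2.01. All had an adjusted p of 1.

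The spleen comparison asked the same question for the organ that filters blood and houses lymphocytes. Cell cycle, plasma cell and neutrophil genes stood higher in KO than in WT spleen, and platelet, erythroid and actin genes stood lower, by list tests that were all lost with an estimated correlation (smallest adjusted p = 0.948). WT spleen held 2 globin-rich libraries against 1 in KO spleen, the reverse of blood. With library kind as a term, neutrophil, cell cycle and plasma cell genes still stood higher, stromal genes stood lower, and the erythroid difference changed sign. In globin-rich spleen libraries alone, with KO 03 as the lone KO library, cell cycle genes lay at -1.49 and plasma cell markers at -0.0245. Neutrophil genes turned to -0.88 without KO 03 and to -0.22 with a replicate block, both without the kind term.

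Cell cycle genes in spleen had a median log2 fold change of 1.75, with 35 of 37 members above 0 (camera adjusted p = 3.2e-11). Plasma cell markers had a median of 0.73 (adjusted p = 0.000113) and neutrophil genes of 0.88 (adjusted p = 0.0149). Platelet markers had a median of -1.73, with 29 of 30 members below 0 (adjusted p = 2.39e-06), and platelet activation signalling genes of -0.35 (adjusted p = 0.000341). Actin and class I myosin genes lay at -0.38 (adjusted p = 0.000756), erythroid genes at -1.79 (adjusted p = 0.0345) and interferon-stimulated genes at -0.23 (adjusted p = 0.0187). In all, 12 of 31 lists passed, 4 up and 8 down. None passed with an estimated correlation (smallest adjusted p = 0.948) or by fry (smallest 0.55).

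With the kind term, 7 lists passed in spleen. Neutrophil genes had a median of 0.84, with 27 of 28 members above 0. Their summed expression was 5940 CPM in KO 03, globin left out, against 1940 CPM or less in every other library of either tissue. Without KO 03 the neutrophil median was -0.88 with genotype alone. It was then 0.87 with the kind term, with 19 of 28 members above 0, but this sets KO 01 and KO 04 against WT 01 alone (sums of 910 and 1220 against 856 CPM). A replicate block without the kind term gave -0.22. Cell cycle genes lay at 0.64 and plasma cell markers at 0.32. Stromal and endothelial markers lay at -0.87, with 32 of 33 below 0, adipose markers at -0.84, coagulation genes at -0.46 and actin genes at -0.16. Stromal sums in the globin-rich spleen libraries were 220 and 200 CPM in WT and 228 CPM in KO, and both WT libraries but not the KO library carried raised olfactory receptor counts (41.5, 38.2 and 3.14 CPM). Platelet markers lay at -0.18 and did not pass. Over the list alone, 6 neutrophil, 2 cell cycle and 1 plasma cell gene were called, against 0 over all genes. No list passed with an estimated correlation (smallest adjusted p = 0.377) or by fry (smallest 0.379).

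No single gene passed in spleen either. edgeR called 0 of 15362 genes, with 370 at an unadjusted p under 0.05 against 768 by chance, and over the list alone it called 0 members. DESeq2 called 0, with 698 genes at an unadjusted p under 0.05, and limma-voom called 0, with 154. With the kind term 0 of 16560 genes were called, with 501 at an unadjusted p under 0.05. As in blood, genotype alone found none of the simulated genes altered 8-fold.

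Spleen genes taken by the same rule are likewise given as values only. Lmnb1, which encodes lamin B1 (ENSMUSG00000024590, plus strand of chromosome 18, 56707813 to 56753424), averaged 27.8 ± 9.43 CPM in WT and 65.5 ± 21.7 CPM in KO spleen (SD, n = 3). Its log2 fold change was 1.23 ± 0.36, and 1.02 ± 0.23 with the kind term. The chromatin protein gene Hmgb2 stood at 1.65 ± 0.53, the spindle gene Kif23 at 1.30 ± 0.38 and the centromere gene Mis18a at 0.93 ± 0.30. The neutrophil granule gene Ngp averaged 9.89 ± 2.46 and 30.9 ± 21.2 CPM (log2 fold change 1.63 ± 0.67), and the iron exporter Slc40a1 stood at 0.71 ± 0.27. The immunoglobulin gene Ighg1 (ENSMUSG00000076614, minus strand of chromosome 12, 113325240 to 113330523) averaged 11.7 ± 19.2 and 153 ± 155 CPM, with a log2 fold change of 3.65 ± 2.03, and 2.48 ± 0.50 with the kind term. Before scaling Ighg1 stood at 84.1, 0.193 and 0.215 CPM in WT and 333, 0.661 and 780 CPM in KO spleen. The kind-term value thus rests largely on WT 01, the lone globin-poor WT library. In blood Ighg1 went the other way with that term, at -1.46 ± 0.58. On the lower side, the platelet granule gene Thbs1 averaged 763 ± 645 CPM in WT and 123 ± 175 CPM in KO spleen, at -2.63 ± 1.62, and at -0.93 ± 0.43 with the kind term. The aquaporin Aqp7 stood at -4.43 ± 1.09 and the glutathione transferase Gstt1 at -4.11 ± 1.06. Before scaling, Gstt1 stood at 20.3, 31.0 and 66.1 CPM in WT and 16.2, 1.65 and 15.4 CPM in KO spleen. Its value thus rests largely on KO 03, the lone globin-rich KO library, against WT 02 and WT 04. Aqp7 stood at 1.55, 2.70 and 1.40 CPM in WT and 0.567, 0.0827 and 0.357 CPM in KO spleen. Mroh7, Dlgap1 and Pappa2 lay between -5.77 and -3.65, on WT means of 2.97 to 3.59 CPM. Before scaling, Dlgap1 and Pappa2 stood at 0.859 to 3.77 CPM in blood WT 01, blood KO 02, spleen WT 02 and spleen WT 04, the 4 libraries with most olfactory receptor counts, and at 0.715 CPM or less elsewhere. The smallest adjusted p in spleen was 0.99.

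Whether NM1 loss acts differently in the tissues was tested as an interaction. Platelet, erythroid, T cell and natural killer genes shifted lower in KO spleen than in KO blood, and cell cycle, plasma cell, neutrophil, stromal and red pulp macrophage genes shifted higher, each relative to WT of its own label. The platelet shift was -2.35 on the log2 scale, with 28 of 30 members below 0 (camera adjusted p = 1.39e-08), and the cell cycle shift 2.55, with 35 of 37 above 0 (adjusted p = 1.87e-08). Of 33 lists 16 passed, none with an estimated correlation (smallest adjusted p = 0.615) or by fry (smallest 0.73). With the kind term the platelet shift was -0.00272, with 15 of 30 members below 0. The neutrophil shift was 1.69, with 28 of 28 members above 0, and 11 of them were called over the list alone against 0 over all genes. Without spleen KO 03 it was 0.97, with 23 of 27 above 0. With all libraries the neutrophil shift gave an adjusted p of 0.152 with an estimated correlation, and 0.803 was the smallest by fry in this fit. With genotype alone, neutrophil medians turned to 0.26 in blood without WT 01 and to -0.88 in spleen without KO 03. Fitted by tissue with the kind term, stromal medians were below 0 in both and lower in spleen than in blood. Cell cycle medians were above 0 in both and lay closer together than with genotype alone.

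At gene level edgeR called 0 of 16858 interactions, with 171 at an unadjusted p under 0.05. DESeq2 called 0, with 510, and limma-voom called 0, with 67. Over the list alone 0 members were called. Across the 14570 genes tested in both tissues, KO effects correlated at r = -0.19. At 10 CPM or more in both tissues r was -0.66 over 8110 genes, and with the kind term it was 0.41 over 15669 genes. These are correlations across genes, which are not independent replicates.

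**Figure D2:**
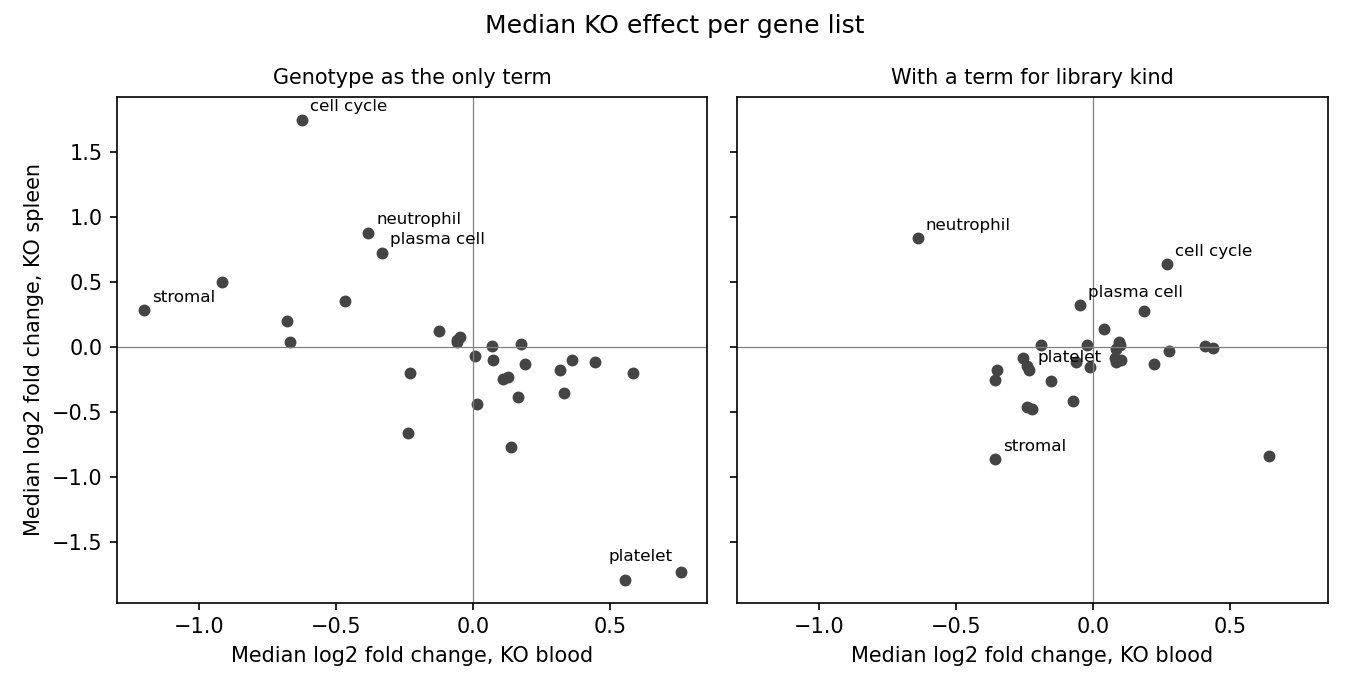
Median log2 fold change of KO over WT per gene list in blood (horizontal axis) and spleen (vertical axis), 1 point per list, with genotype as the only term (left) and with a term for library kind (right). The platelet list moves from 0.76 in blood and -1.73 in spleen on the left to -0.23 and -0.18 on the right, while the neutrophil list lies lower in blood and higher in spleen in both, though on the left it turns to 0.26 in blood without WT 01 and to -0.88 in spleen without KO 03, and to 0.00945 and -0.22 with a replicate block.

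Because globin-rich and globin-poor libraries each held 3 WT and 3 KO samples, genotype was also compared within each kind, across tissue labels. The division into globin-rich and globin-poor was made after the counts were seen. In globin-rich libraries, genes of platelets and red cells stood lower in KO, and B cell, T cell and natural killer genes slightly higher, by list tests that were all lost with an estimated correlation (smallest adjusted p = 0.664). Every one of 30 platelet markers lay below 0, with a median log2 fold change of -0.97 (camera adjusted p = 6e-13), and 13 had an unadjusted p under 0.05. Erythroid genes had a median of -0.52, with 35 of 35 below 0 (adjusted p = 1.9e-05), but within a label it was 0.39 in globin-rich blood and -1.46 in globin-rich spleen, where KO 03 was the lone KO library. Erythroid sums were 145000, 176000 and 166000 CPM in WT and 147000, 164000 and 120000 CPM in KO. Coagulation genes lay at -1 (adjusted p = 3.11e-05), B cell markers at 0.29 (adjusted p = 9.11e-05), T cell markers at 0.21 (adjusted p = 0.00695) and MHC class II genes at 0.26 (adjusted p = 0.0178). In all 10 of 31 lists passed, none with an estimated correlation or by fry (smallest adjusted p = 0.394). Platelet sums were higher under the spleen label, which 2 of the 3 WT but 1 of the 3 KO libraries carried. Counts on olfactory receptor genes were unevenly spread over genotype here, at 62.1, 41.5 and 38.2 CPM in the WT and 55.6, 3.24 and 3.14 CPM in the KO libraries. With the log2 of their sum as a term the platelet median was -1.11 and the erythroid median -0.71, with 30 of 30 and 35 of 35 below 0, and the smallest adjusted p of any list with an estimated correlation was 0.691. Blood KO 02 was the lone KO library with such counts near the WT level. These medians therefore rest largely on it against the 3 WT libraries, 2 of them labelled spleen. With the tissue label as a term, the platelet median was -0.51, again with 30 of 30 below 0 (adjusted p = 3.88e-06, and 0.66 with an estimated correlation). Within a label the platelet median was -0.14 in globin-rich blood (1 WT, 2 KO) and -0.89 in globin-rich spleen (2 WT, 1 KO). Platelet sums there were 10200 CPM in WT against 10000 and 6140 CPM in KO blood, and 17100 and 17900 CPM in WT against 17100 CPM in KO spleen.

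In globin-rich libraries the von Willebrand factor gene Vwf (ENSMUSG00000001930, plus strand of chromosome 6, 125546774 to 125686679) averaged 466 ± 194 CPM in WT and 204 ± 46.7 CPM in KO (SD, n = 3). Its log2 fold change was -1.20 ± 0.40. The megakaryocyte transcription factor Gfi1b stood at -1.77 ± 0.55, Thbs1 at -1.29 ± 0.40, the thrombin receptor F2rl3 at -2.58 ± 0.80 and the ATP receptor P2rx1 at -1.13 ± 0.41. Before scaling, blood KO 02 stood near blood WT 01 in Vwf (307 and 318 CPM) and Thbs1 (278 and 277 CPM). The same held for P2rx1 (52.2 and 52.1 CPM) and F2rl3 (1.09 and 1.05 CPM), but not for Gfi1b (2.72 and 5.61 CPM). Vwf stood at 430 and 396 CPM in spleen WT 02 and WT 04, and at 140 and 274 CPM in blood KO 03 and spleen KO 03. F2rl3 stood at 0.18 CPM in blood KO 03, where 3 counts make 0.27 CPM. The genes with the smallest p were Asf1b, Onecut3, Sez6l2, Col18a1 and Efemp2 on the lower side, from -4.81 to -1.82, and Dnase2a, Sh2b1, Hnrnph3, Creld2 and Irf3 on the higher side, from 0.71 to 1.07. edgeR called 0 of 11728 genes, over all genes and over the list alone, with 799 at an unadjusted p under 0.05 (189 higher, 610 lower) against 586 by chance. With the olfactory receptor term these were 147 higher and 571 lower, and without blood KO 02, the KO library with olfactory receptor counts, 482 genes were called lower. The fit without blood KO 02 cannot tell genotype from the source of those counts. DESeq2 called 0 higher and 31 lower genes, and limma-voom called 0, with 1059 at an unadjusted p under 0.05.

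In globin-poor libraries, plasma cell genes stood higher in KO, and interferon-stimulated, macrophage, dendritic cell, monocyte and stromal genes slightly lower, by list tests that were all lost with an estimated correlation (smallest adjusted p = 0.898). The plasma cell call was also lost with the tissue label as a term (median 0.17, adjusted p = 0.149). Plasma cell markers had a median log2 fold change of 0.48, with 19 of 20 above 0 (camera adjusted p = 2.24e-09). Interferon-stimulated genes lay at -0.19, with 40 of 47 below 0 (adjusted p = 1.62e-05), red pulp macrophage genes at -0.31 (adjusted p = 2.62e-05) and stromal markers at -0.24 (adjusted p = 3.02e-05). Dendritic cell markers lay at -0.24 (adjusted p = 8.76e-05), MHC class II genes at -0.23 (adjusted p = 0.00706) and monocyte markers at -0.17 (adjusted p = 0.00863). The sums of all these lower lists overlapped between WT (blood WT 03, blood WT 04, spleen WT 01) and KO (blood KO 04, spleen KO 01, spleen KO 04). In that order, stromal sums were 2780, 2970 and 5030 against 2290, 3040 and 3950 CPM. Dendritic cell sums were 1210, 1340 and 2210 against 1080, 1370 and 1770 CPM. Spleen WT 01 was highest for stromal, dendritic cell, monocyte and MHC class II sums, but not for interferon-stimulated or macrophage sums. Platelet markers lay at 0.000408, with 15 of 30 below 0 (adjusted p = 0.931). In all 12 of 32 lists passed, none with an estimated correlation or by fry (smallest adjusted p = 0.978). With the tissue label as a term, cell cycle and erythroid genes lay at 1.01 and 1.05, above 0 for all 37 and all 35 members. The labels differed in this: globin-poor blood alone gave an erythroid median of -0.0386 (sums of 24700 and 28000 CPM in WT, 24600 CPM in KO). Globin-poor spleen alone gave 2.21, where spleen WT 01 was the lone WT library (2450 CPM, against 13300 and 6190 CPM in KO). The fit with the tissue label also had no list past with an estimated correlation (smallest adjusted p = 0.517). The difference of the platelet effect between the kinds was -0.92 by camera (adjusted p = 1.21e-05), with an adjusted p of 0.756 with an estimated correlation.

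Ighg1 in globin-poor libraries averaged 56.0 ± 15.3 CPM in WT and 340 ± 336 CPM in KO (SD, n = 3), at a log2 fold change of 2.60 ± 1.12. Before scaling it was 11.1 CPM in the library labelled blood KO 04 and 333 and 780 CPM in spleen KO 01 and KO 04. The monocyte marker gene Cd14 (ENSMUSG00000051439, minus strand of chromosome 18, 36725067 to 36726798) averaged 32.9 ± 7.34 and 15.9 ± 3.39 CPM, at -1.05 ± 0.25, and Il1r2 stood at -1.21 ± 0.45. Mroh7, Crem, Casq2 and Lbhd2 lay between -1.46 and -0.95. Tcrg-C1, Fam227a, Gna14, Rpap1 and Fabp5 lay between 0.50 and 1.36. edgeR called 0 of 16422 genes, over all genes and over the list alone, with 138 at an unadjusted p under 0.05 against 821 by chance. DESeq2 called 5 higher and 0 lower genes, and limma-voom called 0, with 118 at an unadjusted p under 0.05. The 5 were immunoglobulin kappa variable segments outside the naming rule, named after their values were seen: Igkv12-41, Igkv3-2, Igkv14-130, Igkv9-124 and Igkv3-4.

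**Figure D3:**
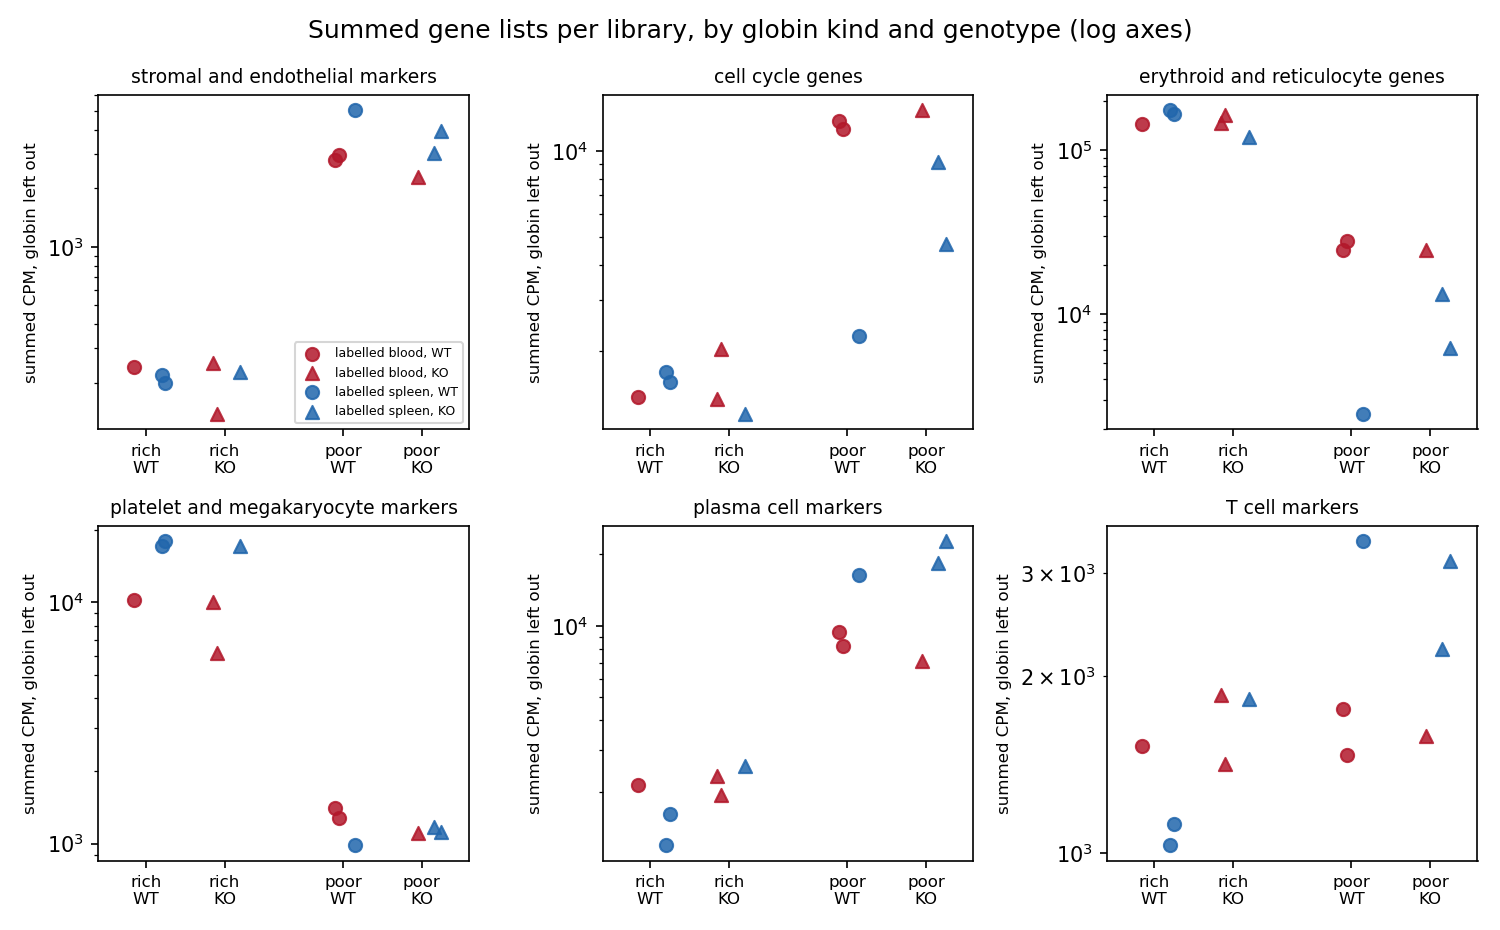
Summed expression of 6 gene lists per library (CPM with globin left out, log axes), by library kind and genotype, with colour for the tissue label. Stromal and plasma cell sums are higher in every globin-poor than in every globin-rich library and platelet and erythroid sums are lower, while WT and KO overlap within most panels.

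Shares of counts did not separate WT from KO. Globin took 19.9 ± 25.0% of counts in WT and 35.4 ± 26.5% in KO blood (SD, n = 3, exact two-sided permutation p = 0.5), and 37.5 ± 31.8% and 19.8 ± 30.3% in spleen (exact p = 0.6). For mitochondrially encoded, ribosomal protein and immunoglobulin constant genes and for the 10 highest genes, the exact p lay between 0.2 and 0.7, with an adjusted p of 0.67 or more over the 10 comparisons. Genes near Myo1c could not be judged by calls, since edgeR called 0 genes anywhere in either tissue. Within 10 Mb of it 1 of 297 tested genes had an unadjusted p under 0.05 in blood, which is 0.337% against 0.157% elsewhere (Fisher's exact p = 0.38, adjusted p = 1). In spleen 5 of 304 did, 1.64% against 2.42% (exact p = 0.57, adjusted p = 1), and counts this small leave the question open.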

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

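The fits with a term for library kind, the fits within a kind and the tests of why library make-up crosses the tissue labels were chosen only after the result was seen.

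For 16 gene lists the KO effect differed between the spleen and blood labels by camera's preset correlation on the interaction term. As spleen minus blood, the median log2 differences were -2.35 for platelet and megakaryocyte markers, -0.42 for platelet activation signalling, -2.53 for erythroid genes, -0.44 for actin and class I myosins, -0.32 for B cell, -0.45 for T cell and -0.68 for cytotoxic and natural killer markers. They were 2.55 for cell cycle genes, 1.5 for plasma cell markers, 1.51 for neutrophil genes, 1.56 for red pulp macrophage and iron genes, 1.61 for stromal and endothelial markers and 1.04 for heat shock genes. Among tissues outside the study they were -5.02 for exocrine pancreas markers, -0.85 for adipose markers and -0.95 for skeletal muscle and skin markers. The pancreas value rests on blood KO 04, whose pancreas sum was 750 CPM against 130 CPM or less in every other library, and without which the blood median was -1.44. With an estimated correlation none passed (smallest adjusted p = 0.615). With a term for library kind 9 lists passed by the preset, none with an estimated correlation (smallest adjusted p = 0.152) or by fry (smallest 0.803), and the platelet difference was -0.00272 while the neutrophil difference was 1.69, both by medians. Stromal medians fitted by tissue with that term were negative in both and lower in spleen, whereas the difference of 1.61 put spleen above blood. Cell cycle medians with it were positive in both tissues.

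Other splits of the libraries gave as much. Of 100 splits for the interaction, 31 gave at least the 16 lists of the real one, with 23 as the highest other, so chance cannot be excluded for the lists. For genes the real count was 0, which all 100 splits reach whatever the data, so the comparison says nothing there (highest other 9625). The split with 9625 genes set globin-rich against globin-poor libraries in both tissues, which points to a structure of the samples. Within a tissue or kind the 10 splits are too few for a share under 0.05, and a real count of 0 genes is again reached by all 10 whatever the data. In blood 5 of the 10 gave at least the real 15 lists (highest other 18), and the highest other gene count was 7816, from the split by library kind. In spleen 9 of the 10 gave at least the real 12 lists (highest other 19), and the highest other gene count was 4411, again from the split by kind. Within globin-rich and within globin-poor libraries the highest other gene counts were 248 and 12. The split with 248 genes set blood WT 01, blood KO 02 and spleen KO 03 against the rest.

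Library make-up crossed the tissue labels in 6 of 12 libraries. The tables argue against genotype, since 50% of the globin-rich libraries were KO, and against blood held in the spleen piece, since stromal markers in the globin-rich libraries labelled spleen reached at most 5.69% of the mean of the globin-poor ones with that label. An exchange of tissue labels stays open and may account for the pattern. As many libraries were out of place under blood as under spleen within each genotype (2 and 2 in WT, 1 and 1 in KO). With 3 libraries of each kind and of each label in every genotype these numbers had to match, so they do not bear on an exchange. Between the tissue labels, 0.073% of genes were called among globin-poor libraries and 0.0085% among globin-rich ones. Those 12 globin-poor genes came from the only split of 10 with any call. Among globin-rich libraries the split by tissue label gave 1 gene, and a split following neither label nor genotype gave 248. Platelet sums (globin-rich) and erythroid sums (globin-poor) did not overlap between the labels. These 2 lists were picked from 33 after their values were seen, and 3 against 3 libraries reach 0.1 at the least. These values therefore cannot decide whether an exchange is the whole account. The labels hold no record of an exchange, so every library kept its label.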

How the results depend on the processing

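The kind term with and without each library, the fits within a kind, the tissue-label and olfactory-receptor terms and the interaction without the 6 libraries at odds with their label were chosen only after the counts were seen. Where no reason is given below, the cause was not tested.

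In blood, spleen and the interaction, edgeR called 0 genes as designed, and 0 under every alternative set beforehand, including DESeq2, limma-voom, the replicate block and each library left out. Unadjusted p under 0.05 then held for 2 to 1290 genes in blood and 78 to 2884 in spleen. Across all alternatives, 214 values of the main results held, 27 moved and 1 reversed. Of the other values 713 held, 115 lost a pass, 7 gained one and 56 reversed. Many of the main values that held were counts of 0 called genes. In simulated data, genotype alone called none of the genes altered 8-fold in blood or spleen, so holding at 0 there says little.

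Under library size only, the median of all genes was -0.61 in blood, 0.69 in spleen, 1.33 in the interaction and 0.33 in globin-rich libraries, against -0.05, 0.02, 0.15 and 0.00 as designed. In blood it reversed platelet activation signalling (-0.48), B cell (-0.42), T cell (-0.30), natural killer (-0.24), erythroid (-0.27), histone (-0.35) and actin genes (-0.50) and Myo1c (-0.507). In spleen it reversed platelet activation signalling (0.41), coagulation (0.0185), interferon-stimulated (0.54), histone (0.66), actin (0.44) and muscle and skin genes (0.50) and Myo1c (0.60).

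With the replicate number as a block, neutrophil genes reversed to 0.00945 in blood and -0.22 in spleen and histones to -0.00172 in blood and 0.0428 in spleen. These fits rest on the 2 numbers that WT and KO share in each tissue.

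With the kind term, these medians reversed in blood: platelet -0.23, platelet activation signalling -0.0623, heat shock 0.0386, cell cycle 0.27 and actin genes -0.00995, as did Myo1c at -0.00995. In spleen erythroid genes (0.28) and Myo1c (0.0572) reversed and 7 lists passed. The kinds are unequally spread over genotype in each tissue, which this term takes out.

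In globin-rich blood libraries alone (1 WT, 2 KO) 1 gene was called higher, Pcx, and 3 lower, Myo15b, Ppp1r3d and Gm26917. Platelet (-0.14), cell cycle (0.0593), actin (-0.0382) and pancreas genes (-1.79) reversed. In globin-poor blood libraries alone (2 WT, 1 KO) 22 genes were called higher and 5 lower, Pdk4, Hdc, Zbtb16, Ighg1 and Ighv5-4. Reversed there were platelet (-0.38), platelet activation signalling (-0.15), B cell (-0.16), T cell (-0.0115), natural killer (-0.20), erythroid (-0.0386), cell cycle (0.24) and actin genes (-0.0671) and Myo1c (-0.27). In globin-rich spleen libraries alone (2 WT, 1 KO) 270 genes were called higher and 1159 lower, and plasma cell (-0.0245) and cell cycle genes (-1.49) and Myo1c (0.31) reversed. In globin-poor spleen libraries alone (1 WT, 2 KO) 20 lists passed, and platelet (0.42), heat shock (-0.0863), erythroid (2.21) and histone genes (1.08) reversed. In these 4 fits the lone library was assumed to vary like the others, so their calls and reversals cannot tell genotype from that 1 library (spleen KO 03, for example, has a neutrophil sum of 5940 CPM against 1940 CPM or less elsewhere), and the genes named were chosen after their values were seen.

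The correlation of KO effects between tissues moved to -0.66 at 10 CPM or more and reversed to 0.41 with the kind term. Myo1c in spleen also reversed with no filter (0.0244) and in 1 fit of all libraries (0.0779). With an estimated correlation and by fry, 0 lists passed in blood and 0 in spleen.

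Leaving out 1 library gave 6 to 17 lists in blood (6 without WT 04, against 15) and 6 to 11 in spleen (6 without WT 04, against 12). It moved neutrophil genes between -0.75 and 0.26 in blood (0.26 without WT 01) and between -0.88 and 1.32 in spleen (-0.88 without KO 03). The same omissions with the kind term gave -0.78 to -0.56 in blood, 0.79 to 1.34 in spleen and 0.97 to 2.09 in the interaction (0.97 without spleen KO 03). Without blood WT 01 or KO 04, or spleen WT 01 or KO 03, each the lone library of its genotype in its kind, these effects rest on 1 library of a genotype and say nothing about stability. Blood histones ranged from -0.10 to 0.42 and pancreas markers from -1.44 to 3.18, both lowest without KO 04, and spleen Myo1c from -0.23 to 0.10, above 0 without WT 04, KO 01 or KO 04.

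In globin-rich libraries 120 genes were called lower with no filter, 16 lists then passed, and DESeq2 called 31 lower. Leaving out 1 library gave 0 to 482 lower genes and 7 to 16 lists, both highest without blood KO 02. Olfactory receptor counts then separated WT (62.1, 41.5 and 38.2 CPM) from KO (3.24 and 3.14 CPM), so that fit cannot tell genotype from their source. In globin-poor libraries DESeq2 called 5 higher, leaving out 1 library gave 6 to 20 lists (6 without blood KO 04, 20 without blood WT 03 or spleen KO 04), and 22 lists passed with the tissue label as a term.

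In globin-rich libraries, which had fewer counts in all and more of them on globin, 11728 genes were tested, against 16422 in the globin-poor libraries.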

Other observations

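The tests of olfactory receptor counts against genotype and all tests of the erythroid and cell cycle genes were chosen only after the result was seen, as was the fit with an olfactory receptor term.

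Olfactory receptor genes, which are mostly silent outside the nose, summed to 62.1 CPM in blood WT 01, 55.6 in blood KO 02, 41.5 in spleen WT 02 and 38.2 in spleen WT 04. They summed to 3.24 and 3.14 CPM in the other 2 globin-rich libraries and to 4.31 to 9.47 CPM in the globin-poor ones. Transcription of a few such genes is argued against, since the 5 highest held at most 14.9% of the family's counts. Genomic DNA carried into the library stays open and may be the source, since Vmn1r, Vmn2r, Tas2r and Krtap genes stood 50.7-fold (95% counting interval 13.8 to 422), 7.54-fold (4.98 to 11.9), 6.62-fold (2.09 to 33.6) and 89.3-fold (15.8 to 3550) higher in the 4 libraries, a median of 29.1-fold. A part for genotype was not decided (WT 47.3 ± 13 CPM, KO 20.7 ± 30.3 CPM, n = 3, exact two-sided permutation p = 0.3). Blood KO 02 at 55.6 CPM lay above spleen WT 02 and spleen WT 04, so the genotypes overlapped. Blood KO 03 and spleen KO 03, at 3.24 and 3.14 CPM, lay below every WT library. With 3 against 3 libraries, which reach 0.1 at the least, this leaves genotype open.

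With the olfactory receptor sum as a term, edgeR called 0 of 12962 genes among globin-rich libraries, with 147 higher and 571 lower at an unadjusted p under 0.05, against 189 and 610 of 11728 without it.

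Across the 6 globin-poor libraries, erythroid and cell cycle sums moved together (r = 0.99, exact permutation p = 0.0083, adjusted p = 0.021 over 6 relations, rho = 0.771 with exact p = 0.1). Both sums were lower in every library labelled spleen (erythroid 2450 to 13300 CPM, cell cycle 2250 to 9140 CPM) than in every one labelled blood. The permutations treated the libraries as interchangeable and ignored the tissue label. The exact p-values of this paragraph therefore cannot tell a link between lists from a difference between labels. Without spleen WT 01 and spleen KO 04, the farthest from the median, r was 0.86, but this rests on spleen KO 01 against the 3 libraries labelled blood, within which the sums ran opposite ways (erythroid 24700, 28000 and 24600 CPM, cell cycle 12700, 11900 and 13900 CPM). Blood held in the tissue is argued against, since cell cycle genes summed to at most 2020 CPM in globin-rich libraries and to at least 2250 CPM in globin-poor ones. Genotype cannot be told apart: it took 0.1% of the variance of the erythroid sum but 35.5% of what the tissue label left, and globin-poor libraries alone gave erythroid medians of -0.0386 in blood and 2.21 in spleen, where spleen WT 01 was the lone WT library. A varying share of dividing red cell precursors stays open and may link them, as a hypothesis found and tested on the same 6 libraries. T cell markers ran against the erythroid sum (r = -0.96, exact p = 0.0028, -0.95 without those 2), as did B cell (-0.96, then -0.46), stromal (-0.94, then -0.39) and plasma cell markers (-0.75, then -0.94), while platelet markers ran with it (0.79, then 0.37).

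Pancreas and fat cell genes each stood out in 2 libraries. The pancreatic trypsinogen gene Prss2 stood at 47.0 CPM in blood KO 04 (Wilson interval 44.4 to 49.9) and at 8.30 CPM in blood WT 04 (7.24 to 9.52), and at or under 0.357 CPM in every other library. The fat cell gene Adipoq stood at 30 CPM in spleen WT 01 (27.9 to 32.2) and 31.6 CPM in spleen KO 04 (29.5 to 33.9), and at or under 3.27 CPM elsewhere. Xist stayed under 2 CPM and the Y-linked gene Ddx3y between 12.1 and 134 CPM in every library.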
